A study of Homo sapiens with 30 samples.

How the data were processed

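The series holds RNA sequencing of primary human hepatic stellate cells used before passage 3, in 10 groups of 3 libraries. The groups are untreated cultures with vehicle at 0, 24, 48 and 72 h, cultures with TGF-β1 at 24, 48 and 72 h, and cultures with TGF-β1 plus JQ1 at the same times. Libraries were made from 1 μg of RNA with a directional kit and sequenced in pairs of reads. The strand setting of the counting and the doses are not given in the sources used here.

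Per the labels, the authors named STAR 2.5.2, featureCounts and Subread 1.5.1 and the genome build GRCh38, with no role or order for each. The deposited values are FPKM with 3 decimals for 60498 genes, 1 file per library, made by the authors with a program that is not stated. The product of FPKM and gene length in kb sums to 1 total in every library, so the values are relative to the fragments assigned to genes. A matrix of the whole series was not used, because 9 of its columns match no sample. Counts were not available, so tests made for counts were not run as main tests.

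The depth of each library was recovered from the steps between low values, since FPKM times length must be a whole number of fragments. It ran from 37240000 to 54790000 assigned fragments. At this depth 99.72 to 100% of the 10408 to 14244 low values used per library lay within 1.05 rounding half-steps of a whole number, against at most 9.8% at a depth 5% higher. At these depths 3 fragments on a gene of 1 kb equal 0.0548 to 0.0805 FPKM. Between replicates, chi-square per degree of freedom over genes with at least 50 fragments had a median of 6.97 (2.82 to 31.9 over 30 pairs), and 0 pairs were identical. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these libraries, which can be technical.

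Genes with at least 1 FPKM in at least 3 of the 30 libraries were tested (13875 genes). Values were log2 of FPKM + 0.5, which shrinks the differences of genes with low values. All 30 libraries entered a single limma fit with 1 mean per group and a variance trend over the mean level (median residual SD 0.082 log2, prior df 3.1, median total df 23.1). Contrasts were TGF-β1 against untreated, TGF-β1 plus JQ1 against TGF-β1 and against untreated at each time, untreated at each later time against 0 h, and the difference between 72 and 24 h of the TGF-β1 and of the JQ1 effect. The p-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05, tests were two-sided, and a second count asked for at least a 2-fold difference. Opposite calls of the TGF-β1 and JQ1 effects were counted and set beside the overlap of independent lists and 50 simulations of unchanged groups.

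Gene lists were written before the data were examined, as were the contrasts, thresholds, named-gene rule and most alternative settings. The 22 program lists and 7 marker lists of other cell types (hepatocyte, cholangiocyte and epithelial, endothelial, macrophage and Kupffer cell, lymphocyte, mesothelial, portal fibroblast and vascular smooth muscle) held 489 entries, of which 405 were tested. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over the 22 program lists in each contrast. Symbols were matched by gene name in the files and older names by alias. Near copies, such as histone, metallothionein and ferritin genes, share reads, so single members are less certain than the group.

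The named genes are 18 anchors known from fibrosis or BET inhibition and genes chosen by rule. For both main comparisons the rule took up to 2 members per program list with the largest mean difference and 1 sign at all 3 times, and the 5 largest mean rises and falls among genes with at least 5 FPKM in the higher group. For TGF-β1 plus JQ1 against untreated and untreated cultures over time it took 4 rises and 4 falls, for the differences between 72 and 24 h 4 positive and 4 negative genes, and for opposite calls 6 genes raised and then lowered at all 3 times and 6 raised and lowered at none. Both sets of 6 were ordered by the mean TGF-β1 rise alone. Genes of chromosome Y, XIST and genes named after clones were left out of this rule. Of the named genes 3 are not reported here, and counts of named genes leave them out.

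The pipeline was tested on simulated data. With 12659 simulated genes and 3 libraries per group, 65 of 67 genes changed 1.5-fold and 67 of 67 changed 2-fold were called, and 7 of 12459 unchanged genes were called. The simulation changed few genes, up and down alike in a single group, with the same dispersion for every gene. It does not show the error rate where most genes change or where the balance depends on scaling. Alternatives were a pseudocount of 0.1 or 1, no filter, a filter at 5 FPKM, TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, limma without the trend, array weights, fits on the compared groups alone, and leaving out each library. Precision weights on recovered fragments (voom) and a fit of protein-coding genes alone were added after the data were seen. Tools were R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.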

Results

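RNA sequencing was available for 30 libraries of primary human hepatic stellate cells, the liver cells that turn into matrix-producing myofibroblasts during fibrosis. The cells were cultured with vehicle (DMSO, called untreated here), with TGF-β1, a cytokine that drives this activation, or with TGF-β1 together with JQ1. JQ1 is a small molecule that displaces BET bromodomain proteins from acetylated chromatin. Untreated cultures were sampled at 0, 24, 48 and 72 h and both treated arms at 24, 48 and 72 h, with 3 libraries in each of 10 groups. An arm with JQ1 alone was not analysed here, so each JQ1 effect is an effect on top of TGF-β1, and the doses are not given in the sources used here.

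The deposited values are FPKM, fragments scaled to gene length and to the assigned fragments of the library. At the recovered depths 3 fragments on a gene of 1 kb equal 0.0548 to 0.0805 FPKM. Each library held 11078 to 12163 genes at 1 FPKM or more. Levels are given as mean ± SD over 3 libraries. Differences are log2 differences of FPKM + 0.5 from a limma fit over 13875 genes, in the order 24, 48 and 72 h where 3 values follow each other. A gene rose or fell when its adjusted p passed the 0.05 threshold. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these libraries, which was small (median residual SD 0.082 on the log2 scale).

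TGF-β1 against untreated cultures at the same time addresses which genes differ with added TGF-β1. The untreated cultures also changed with time, as given below, so this is not activation against a resting state. FN1, which encodes the matrix protein fibronectin, reached 4585 ± 73.5 FPKM with TGF-β1 at 72 h against 1445 ± 154 in untreated cultures. The log2 differences were 0.58, 1.04 and 1.67 (SE 0.057 and adjusted p = 7.35e-18 at 72 h). COL1A1, which encodes the main chain of fibrillar collagen, was higher at 48 h, at 7383 ± 40.8 against 5093 ± 115 FPKM (0.54, SE 0.082, adjusted p = 6.61e-06). It differed by 0.10 and -0.10 at 24 and 72 h without passing, except at 24 h with array weights (0.102). ACTA2, which encodes the smooth muscle actin used as the marker of myofibroblasts, rose by 0.39 and 0.72 at 24 and 48 h and fell at 72 h (-0.89). At 72 h it stood at 101 ± 4.86 FPKM with TGF-β1 and 189 ± 30.9 FPKM in untreated cultures. In the GRCh38 files these genes are FN1 (ENSG00000115414.18, chromosome 2, 215360440 to 215436172, minus strand), COL1A1 (ENSG00000108821.13, chromosome 17, 50183289 to 50201632, minus strand) and ACTA2 (ENSG00000107796.12, chromosome 10, 88935074 to 88991390, minus strand).

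Among the matrix genes, 4, 11 and 10 of 20 measured collagen chains rose at the 3 times and 10, 7 and 9 fell (camera adjusted p = 0.636, 0.00069 and 0.388, and adjusted p = 0.289 with an estimated correlation at 48 h). COL7A1, which encodes the anchoring fibril collagen, rose by 1.19, 1.62 and 1.94, while COL14A1, which encodes a fibril-associated collagen, and COL3A1 fell (-1.27, -2.08 and -2.12 and -0.51, -0.34 and -0.64). COL1A2 fell at 24 and 72 h (-0.17 and -0.19), calls that median-of-ratios scaling ended (-0.079 and -0.148). It rose at 48 h (0.26), a difference that quantile normalization brought to 0. Of 22 matrix glycoproteins and proteoglycans, 9, 12 and 10 rose and 9, 8 and 12 fell (adjusted p = 0.0684, 0.00101 and 0.711, and adjusted p = 0.177 with an estimated correlation at 48 h). POSTN, which encodes the matricellular protein periostin, rose by 1.41, 0.93 and 1.70 to 90 ± 3.52 FPKM at 72 h, against 27.4 ± 0.682 in untreated cultures. TNXB, which encodes tenascin-X, and ASPN, which encodes the small proteoglycan asporin, fell at each time (-2.48, -3.43 and -3.44 and -1.38, -2.29 and -3.33). Of 18 genes for collagen modification and crosslinking, 7, 12 and 5 rose and 4, 3 and 9 fell (adjusted p = 0.0701, 1.17e-06 and 0.381, and adjusted p = 0.0485 with an estimated correlation at 48 h). The prolyl hydroxylase subunit gene P4HA3 rose (0.74, 1.40 and 0.51), and the lysyl oxidase gene LOX did not pass at any time (-0.08, 0.04 and -0.03). LOX passed at 48 h with median-of-ratios scaling (0.159) and at 24 h with array weights (-0.09). The related LOXL1 fell at each time (-0.79, -0.21 and -2.01), and its 48 h call was lost with each other scaling (-0.179 with TPM, -0.091 with median-of-ratios scaling and -0.106 with quantile normalization). Matrix proteases and their inhibitors did not pass as a list, with 4, 4 and 5 of 15 up and 8, 4 and 5 down (adjusted p = 0.104, 0.622 and 0.791). In that list the aggrecanase genes ADAMTS1 (-1.63, -2.84 and -1.59) and ADAMTS5 (-1.90, -1.76 and -0.62) fell, and TIMP1, an inhibitor of matrix metalloproteinases, rose by 0.18, 0.59 and 0.17. Its 24 and 72 h calls were lost without the filter.

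Of 17 contractile and cytoskeletal genes, 11, 11 and 2 rose and 4, 2 and 14 fell, with a list median of -0.89 at 72 h (camera adjusted p = 0.00191, 0.000184 and 0.00113, and adjusted p = 0.3, 0.177 and 0.258 with an estimated correlation). LMOD1, which encodes the actin-binding protein leiomodin, and VCL, which encodes vinculin, fell at each time (-0.73, -1.80 and -2.77 and -0.25, -0.61 and -1.24). Markers of portal fibroblasts and vascular smooth muscle moved with this list, 2, 3 and 0 of 5 measured markers being up and 2, 1 and 5 down at the 3 times. The 72 h fall passed (adjusted p = 0.00095, and adjusted p = 0.0488 with an estimated correlation). Among those 5 markers CNN1 also belongs to the contractile list. SMAD targets and feedback genes were up in 13, 15 and 11 of 17 cases and down in 2, 1 and 3 (camera adjusted p = 8.21e-09, 6.73e-11 and 0.0279, and adjusted p = 0.0111, 0.00888 and 0.298 with an estimated correlation). DACT1, which encodes a modulator of Wnt signalling, and PMEPA1, a negative regulator of TGF-β signalling, rose by 1.32, 1.32 and 1.496 and 1.38, 1.24 and 0.87. The inhibitory SMAD gene SMAD7 rose by 0.56 and 0.55 and did not pass at 72 h (0.03), and TGFB1 rose by 0.39 and 0.30 and then fell (-0.62). CTGF, which encodes connective tissue growth factor, rose by 1.61 and 0.40 and then fell (-2.06 at 72 h). Of 10 BMP and ID target genes, 1, 1 and 2 rose and 8, 8 and 8 fell (adjusted p = 0.0128, 0.0134 and 0.0393, and adjusted p = 0.0868, 0.104 and 0.214 with an estimated correlation). The receptor decoy BAMBI and the differentiation inhibitor ID1 fell (-1.35, -1.55 and -1.48 and -1.23, -1.10 and -1.83).

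Genes of quiescent stellate cells and retinoid handling fell in 12, 15 and 15 of 17 cases and rose in 2, 1 and 2 (camera adjusted p = 0.000303, 2.48e-06 and 0.000877, and adjusted p = 0.0314, 0.00908 and 0.0931 with an estimated correlation). COLEC11, which encodes a collectin, fell from 101 ± 6.98 FPKM in untreated cultures to 15.4 ± 0.842 FPKM at 72 h, and HAND2, a transcription factor gene, fell at each time (-0.76, -1.40 and -2.13). PDGFRB, which encodes the PDGF receptor of mesenchymal cells, fell as well (-0.37, -0.36 and -1.07). All 5 measured endothelial markers fell beside them at each time (adjusted p = 0.000259, 0.0132 and 0.00128, and adjusted p = 0.00496, 0.0483 and 0.0176 with an estimated correlation). The highest group means were 52.7 FPKM for KDR and 10.2 FPKM for PECAM1. Interferon-stimulated genes fell in 15 of 17 cases at 24 h, and at 48 and 72 h 2 and 9 rose while 8 and 4 fell (adjusted p = 0.000158, 0.501 and 0.0393, and adjusted p = 0.0105 and 0.208 with an estimated correlation at 24 and 72 h). The 72 h call of this list was lost without untreated 72 h replicate 1 (median 0.18). BST2, which encodes the virus-tethering protein tetherin, and OAS2, an antiviral enzyme gene, fell at each time (-1.14, -0.50 and -0.24 and -0.82, -0.32 and -0.24). Their 72 h calls were lost with TPM for BST2 (-0.176) and with quantile normalization for OAS2 (-0.024). Of 20 inflammatory cytokine and NF-κB target genes, 9, 14 and 13 rose and 5, 5 and 6 fell (adjusted p = 0.052, 1.84e-06 and 0.024, and adjusted p = 0.0251 and 0.258 with an estimated correlation at 48 and 72 h). The cytokine gene LIF rose (0.64, 1.70 and 1.68) and IL1B, which encodes interleukin-1β, fell (-1.11, -1.44 and -1.61).

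All 15 measured ATF4 targets and genes of serine, glycine and proline synthesis rose at 48 h, with a list median of 1.91, against 11 up and 1 down at 24 h and 11 up and 3 down at 72 h. The list passed at each time (adjusted p = 4.34e-10, 2.07e-26 and 0.00521, and adjusted p = 0.0105, 3.08e-05 and 0.214 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, went from 0.749 ± 0.0973 to 24.3 ± 0.723 FPKM at 48 h, and SLC7A5, which encodes a subunit of an amino acid transporter, rose by 1.77, 3.55 and 1.02. Of 21 cholesterol and fatty acid synthesis genes, 18 rose at 24 h, while 20 and 21 fell at 48 and 72 h (adjusted p = 2.39e-10, 2.01e-08 and 8.83e-12, and adjusted p = 0.0314, 0.0485 and 0.0544 with an estimated correlation). P53 targets fell in 13 of 17 cases at 24 h and rose in 8 and 16 at 48 and 72 h (adjusted p = 0.00191, 0.000939 and 9.65e-10, and adjusted p = 0.0105, 0.00888 and 1.93e-05 with an estimated correlation). The nuclease gene AEN rose (0.32, 0.44 and 1.25). Of 15 endoplasmic reticulum chaperone and unfolded protein response genes, 9, 6 and 12 rose and 0, 6 and 2 fell (adjusted p = 3.23e-06, 0.0145 and 2.65e-05, and adjusted p = 0.0391, 0.273 and 0.122 with an estimated correlation). HSPA5, which encodes the chaperone BiP, reached 821 ± 35.3 FPKM at 72 h against 199.5 ± 16.5, and HYOU1, another chaperone gene, rose by 0.58, 0.47 and 1.57. Autophagy and lysosome genes fell in 13 and 13 of 18 cases at 24 and 48 h and rose in 12 at 72 h (adjusted p = 0.00138, 0.0215 and 0.00521, and adjusted p = 0.0466, 0.172 and 0.151 with an estimated correlation). ATG2A, a lipid transfer gene of autophagy, fell at each time (-0.26, -0.36 and -0.36), its 24 h call being lost with median-of-ratios scaling (-0.178) and quantile normalization (-0.184).

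Proliferation genes were up in 17 of 28 cases at 24 h and down in 26 at 72 h, with 6 up and 10 down at 48 h, or 10 up and 6 down with quantile normalization. Camera passed the list at 24 and 72 h (adjusted p = 0.000245, 0.332 and 2.29e-08, and adjusted p = 0.351 and 0.23 with an estimated correlation at 24 and 72 h). Of 20 MYC and ribosome biogenesis genes, 19, 13 and 9 rose and 0, 0 and 4 fell (adjusted p = 2.13e-12, 1.17e-06 and 0.174, and adjusted p = 0.0105 and 0.0485 with an estimated correlation at 24 and 48 h). ODC1, the first enzyme of polyamine synthesis, and NOP16, a nucleolar protein gene, rose (0.43, 0.81 and 1.46 and 0.74, 0.55 and 0.36). MYC rose by 0.32, 0.38 and 0.11. AP-1 and immediate early genes rose in 2, 9 and 11 of 15 cases and fell in 2, 2 and 2 (adjusted p = 0.114, 1.23e-05 and 0.00113, and adjusted p = 0.114 and 0.258 with an estimated correlation at 48 and 72 h). JUNB and IER3 rose (1.08, 1.28 and 0.97 and 0.56, 0.86 and 0.53). YAP and TAZ targets fell in 10, 10 and 12 of 18 cases and rose in 5, 4 and 4 (adjusted p = 0.459, 0.825 and 0.0437, and adjusted p = 0.324 with an estimated correlation at 72 h). The 72 h call was lost without untreated 72 h replicate 2 (median -0.52). RBMS3 and ARHGEF17 fell (-0.89, -0.90 and -0.55 and -0.48, -0.56 and -0.90). Growth factors and receptors did not pass (8, 6 and 7 of 21 up, 10, 13 and 13 down, adjusted p = 0.636, 0.622 and 0.183), and quantile normalization turned their 24 h counts to 8 up and 7 down. VEGFA, the vascular growth factor gene, rose (1.27, 1.80 and 0.99), and the IGF-binding protein gene IGFBP5 fell (-1.22, -2.45 and -3.34). Histone genes fell in 10, 7 and 3 of 14 cases and rose in 0, 1 and 7 (adjusted p = 0.0276, 0.552 and 0.14, and adjusted p = 0.3 with an estimated correlation at 24 h). This call was lost without untreated 24 h replicate 3 (median -0.31). HIST1H1C, a linker histone gene, fell (-0.62, -0.65 and -0.93). BET proteins and P-TEFb regulators did not pass as a list (0, 1 and 5 of 10 up, 4, 6 and 4 down, adjusted p = 0.164, 0.443 and 0.268), and HEXIM1, which encodes the inhibitor of P-TEFb, fell (-0.24, -0.46 and -0.30). Of genes of BET proteins, BRD3 fell at 48 and 72 h (-0.21 and -0.09), and median-of-ratios scaling ended both calls (-0.096 and -0.05). BRD2 fell at 24 and 48 h (-0.19 and -0.15), the 48 h call being lost with that scaling (-0.032), and rose by 0.39 at 72 h.

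Over all genes, the largest mean rises with TGF-β1 at the 3 times included MSC, which encodes the repressor musculin (1.38, 2.05 and 2.87), VDR, the vitamin D receptor gene (1.70, 2.16 and 2.43), FIBIN (1.51, 2.03 and 2.37) and FAM46A (0.49, 1.39 and 3.73). The largest mean falls included CLDN11, which encodes a tight junction protein (-0.88, -3.52 and -4.66), the growth arrest gene GAS1 (-1.97, -2.43 and -3.10) and PDK4, which encodes a kinase that restrains pyruvate oxidation (-3.02, -2.51 and -1.54). At 24, 48 and 72 h, 7383, 7540 and 9603 of 13875 genes passed, 264, 500 and 1260 of them with at least a 2-fold difference. These 2-fold counts moved with the settings. They were 530, 751 and 1842 with a pseudocount of 0.1, 165, 362 and 882 with a pseudocount of 1, 511, 734 and 1783 with TPM and 688, 828 and 2047 with voom. Up were 2496, 1950 and 4263 and down 4887, 5590 and 5340, and 591 genes rose and 2093 fell at all 3 times. Camera passed 13, 15 and 14 of the 22 lists, and 9, 8 and 1 with an estimated correlation. Adjusted over the list alone, 14 SMAD, 8 collagen modification and 12 ATF4 genes were up at 24 h, and 10 matrix, 16 interferon, 14 p53 and 14 quiescence genes were down. At 48 h these counts were 13 collagen modification genes up, and 3 contractile, 8 histone and 14 autophagy genes down, and at 72 h 17 p53 and 13 autophagy genes up. The other counts adjusted over the list alone equalled those over all genes. The excess of falls depended on scaling. With median-of-ratios scaling 3695 genes were up and 3619 down at 24 h, and 3430 up and 3558 down at 48 h, where the median over all genes moved from -0.111 to -0.005. Quantile normalization gave more genes up than down at each time (3504 and 3190, 3632 and 3522, and 5196 and 4405), and TPM did at 72 h (4877 and 4750).

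**Figure D1:**
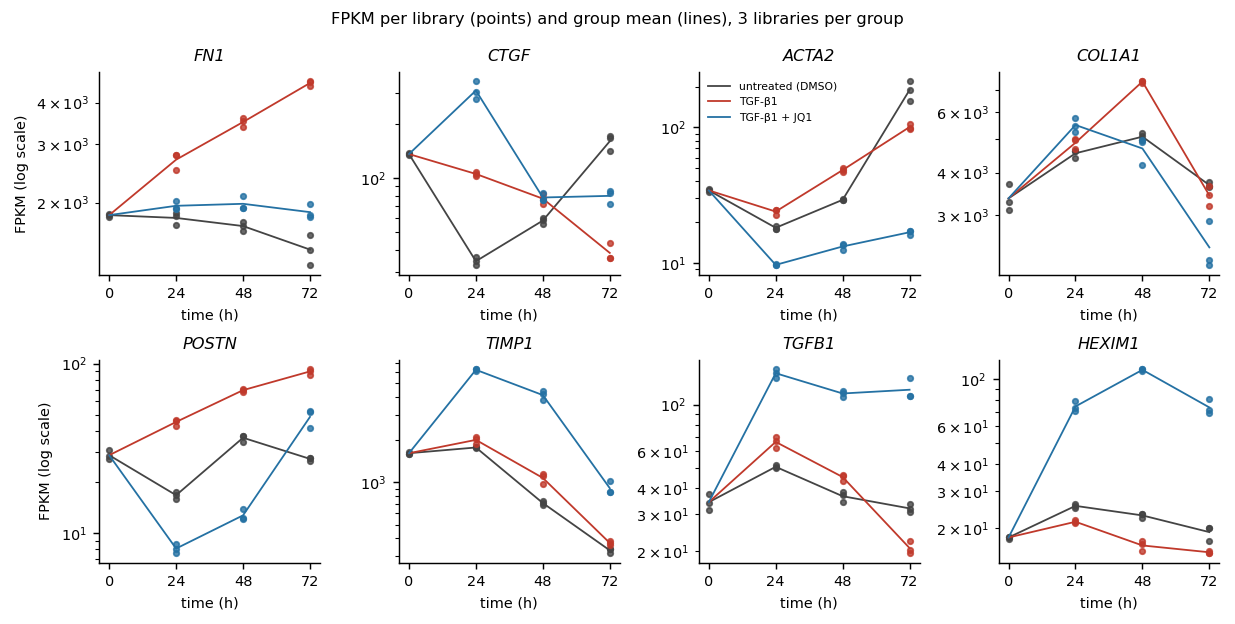
FPKM on a log scale against time in h for 8 genes, with 1 point per library, 3 libraries per group and lines through the group means, for untreated, TGF-β1 and TGF-β1 plus JQ1 cultures. FN1 reached 4585 FPKM with TGF-β1 at 72 h and 1873 with JQ1, ACTA2 reached 189 FPKM in untreated cultures at 72 h, and HEXIM1 reached 111 FPKM with JQ1 at 48 h.

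Untreated cultures at 24, 48 and 72 h against 0 h show what the cells did in culture without added TGF-β1. TOP2A, which encodes the DNA topoisomerase of dividing cells, went from 132 ± 7.16 FPKM at 0 h to 2.67 ± 0.66 FPKM at 72 h (-1.43, -4.66 and -5.41, SE 0.11 and adjusted p = 6.04e-23 at 72 h). UBE2C, which encodes a ubiquitin-conjugating enzyme of mitosis, fell at each time (-1.47, -4.36 and -4.93). ACTA2 was lower at 24 and 48 h (-0.90 and -0.23) and rose by 2.43 at 72 h, from 34.4 ± 0.97 to 189 ± 30.9 FPKM. COL3A1, a fibrillar collagen chain gene, rose by 0.61, 1.66 and 1.25, to 6329 ± 137 FPKM at 48 h.

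Of 28 proliferation genes, 25, 28 and 28 fell and none rose, with list medians of -0.83, -3.71 and -4.41 (camera adjusted p = 2e-10, 1.74e-14 and 6.65e-17, and adjusted p = 0.132, 0.0826 and 0.129 with an estimated correlation). MYC and ribosome biogenesis genes fell in 19, 19 and 19 of 20 cases and rose in 0, 0 and 1 (adjusted p = 1.5e-10, 4.12e-08 and 9.19e-07, and adjusted p = 0.0278, 0.0826 and 0.129 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 20, 20 and 19 of 21 cases with none down (adjusted p = 3.76e-07, 3.85e-06 and 1.79e-06, and adjusted p = 0.0878, 0.0865 and 0.199 with an estimated correlation). Histone genes rose in 14, 11 and 10 of 14 cases with none down (adjusted p = 2.84e-06, 0.000464 and 0.00836, and adjusted p = 0.0324, 0.0865 and 0.267 with an estimated correlation). Autophagy and lysosome genes rose in 16, 15 and 14 of 18 cases against 0, 2 and 2 down (adjusted p = 3.2e-05, 0.000464 and 0.00205, and adjusted p = 0.0285, 0.0826 and 0.129 with an estimated correlation). Contractile genes were up in 4, 5 and 13 of 17 cases and down in 11, 10 and 1 (adjusted p = 0.0088, 0.335 and 0.000612, and adjusted p = 0.31 and 0.267 with an estimated correlation at 24 and 72 h). Quiescence genes rose in 10, 13 and 11 of 17 cases and fell in 2, 4 and 5 (adjusted p = 0.142, 0.00391 and 0.0682, and adjusted p = 0.0826 with an estimated correlation at 48 h), and PDGFRB rose beside them (1.41, 2.49 and 2.65). Interferon-stimulated genes rose in 15, 14 and 10 of 17 cases and fell in 2, 2 and 4 (adjusted p = 0.00276, 0.00483 and 0.0766, and adjusted p = 0.0324 and 0.0826 with an estimated correlation at 24 and 48 h). P53 targets rose in 15, 10 and 10 of 17 cases and fell in 1, 3 and 5 (adjusted p = 1.68e-05, 0.0763 and 0.129, and adjusted p = 0.00174 with an estimated correlation at 24 h). In the ranking limited as above, the largest mean rises were those of the microRNA gene MIR503 (2.25, 4.51 and 5.08), C10orf10 (2.08, 3.84 and 3.76), PIK3IP1 (2.58, 3.82 and 3.07) and TNFRSF21 (1.93, 3.86 and 3.42). Large mean falls included the immediate early gene FOS (-4.18, -4.23 and -3.74) and the mitochondrial transfer RNA gene MT-TI (-3.68, -4.07 and -3.24). MIR503 and MT-TI are short RNAs that this library type measures poorly.

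Against 0 h, 9421, 11211 and 11049 of 13875 genes passed at 24, 48 and 72 h (5401, 5516 and 5566 up, 4020, 5695 and 5483 down), 828, 3058 and 2654 with at least a 2-fold difference. The 24 h count of 828 became 1466 with a pseudocount of 0.1, 510 with 1, 1421 with TPM and 1742 with voom. All 3 times are set against the same 3 libraries at 0 h. Camera passed 16, 10 and 8 lists, and 6, 0 and 0 with an estimated correlation. Adjusted over the list alone, 26 proliferation genes were down and 6 contractile genes up at 24 h and 20 cholesterol genes up at 72 h, with equal counts for the other lists named in this comparison. With median-of-ratios scaling the 24 h counts turned to 4492 up and 5006 down. The 48 h counts turned to 5729 up and 5522 down with that scaling, 5617 and 5421 with quantile normalization and 5932 and 5225 with TPM.

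TGF-β1 plus JQ1 against TGF-β1 at the same time addresses which genes the BET inhibitor changes in the presence of TGF-β1. HEXIM1, which encodes the inhibitor of P-TEFb and is a known marker of BET inhibition (ENSG00000186834.3, chromosome 17, 45148502 to 45152101, plus strand), stood at 111 ± 1.33 FPKM with JQ1 at 48 h against 16.6 ± 0.951 with TGF-β1 alone. Its log2 differences were 1.77, 2.70 and 2.22 (SE 0.052 and adjusted p = 5.25e-23 at 48 h). ACTA2 fell at each time (-1.26, -1.83 and -2.54), to 16.9 ± 0.603 FPKM at 72 h, and FN1 fell (-0.46, -0.82 and -1.29) to 1873 ± 91.4 FPKM at 72 h. TIMP1 rose instead, to 6242 ± 108 FPKM at 24 h against 1992 ± 109 (1.65, 1.95 and 1.28). TGFB1, the gene of the cytokine itself, rose as well (1.08, 1.31 and 2.48).

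Collagen chains fell in 13, 16 and 15 of 20 cases and rose in 3, 4 and 3 (camera adjusted p = 0.242, 1.41e-05 and 0.000676, and adjusted p = 0.25 and 0.318 with an estimated correlation at 48 and 72 h). COL1A2 fell at each time (-0.56, -1.23 and -0.92), and COL1A1 fell at 48 and 72 h (-0.66 and -0.52) after 0.17 at 24 h without passing. COL3A1 fell (-1.07, -1.64 and -0.21). Quantile normalization turned the COL3A1 difference at 72 h to 0.05. COL1A1 at 24 h passed as lower with quantile normalization (-0.62) and as higher with median-of-ratios scaling (0.287), array weights (0.123), the compared groups alone, voom and protein-coding genes alone (0.172 each). The largest falls in this list were those of COL16A1, a fibril-associated collagen chain (-2.23, -4.33 and -4.87), and COL15A1, a basement membrane collagen chain (-1.02, -3.59 and -5.99). Matrix glycoproteins and proteoglycans fell in 14, 19 and 16 of 22 cases and rose in 4, 3 and 5 (adjusted p = 0.165, 2.65e-07 and 0.00657, and adjusted p = 0.0646 and 0.302 with an estimated correlation at 48 and 72 h). POSTN fell (-2.42, -2.41 and -0.89), as did LTBP2, which encodes a latent TGF-β binding protein (-2.07, -3.39 and -3.72), while TNXB rose (1.00, 3.10 and 5.30) to 154 ± 12.1 FPKM at 72 h. Genes for collagen modification and crosslinking fell in 9, 11 and 10 of 18 cases and rose in 4, 6 and 6 (adjusted p = 0.38, 0.0245 and 0.171, and adjusted p = 0.296 with an estimated correlation at 48 h). LOX and LOXL3, both lysyl oxidase genes, fell (-0.76, -1.06 and -1.50 and -2.46, -2.81 and -1.61), as did the procollagen processing enhancer gene PCOLCE (-1.66, -2.42 and -2.67). Of 15 proteases and inhibitors, 8, 7 and 8 rose and 5, 6 and 5 fell (adjusted p = 0.175, 0.676 and 0.391). PLAT, which encodes tissue plasminogen activator, rose (1.86, 2.54 and 3.31) and the aggrecanase gene ADAMTS4 fell (-1.50, -1.84 and -2.42).

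Contractile genes fell in 10, 13 and 13 of 17 cases and rose in 3, 4 and 3 (camera adjusted p = 0.466, 0.00278 and 0.0057, and adjusted p = 0.296 and 0.318 with an estimated correlation at 48 and 72 h). MYL9, a myosin light chain gene, fell at each time (-1.27, -2.62 and -4.28). Portal fibroblast and smooth muscle markers beside them were down in 4, 4 and 2 of 5 and up in 0, 0 and 3 (adjusted p = 0.212, 0.0507 and 0.763). SMAD targets fell in 9, 11 and 12 of 17 cases and rose in 4, 2 and 4 (adjusted p = 0.934, 0.00278 and 0.0328, and adjusted p = 0.25 and 0.318 with an estimated correlation at 48 and 72 h). The transcription factor gene BHLHE40 fell (-0.57, -3.01 and -2.36), and CTGF rose at 24 h (1.54) and at 72 h and did not pass at 48 h (0.02). BMP and ID targets rose in 4, 7 and 8 of 10 cases and fell in 3, 3 and 2 (adjusted p = 0.158, 0.142 and 0.0152, and adjusted p = 0.141 with an estimated correlation at 72 h). ID1 rose (2.59, 2.68 and 3.82) and the BMP antagonist gene GREM1 fell (-2.55, -4.72 and -4.11). Quiescence and retinoid genes rose in 4, 8 and 12 of 17 cases and fell in 11, 7 and 5 (adjusted p = 0.377, 0.585 and 0.0152, and adjusted p = 0.188 with an estimated correlation at 72 h). RARB, a retinoic acid receptor gene, rose at each time (0.85, 2.84 and 3.17), and PDGFRB fell at 24 and 48 h (-2.34 and -1.55) and rose by 0.72 at 72 h.

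Inflammatory cytokine and NF-κB target genes fell in 20, 16 and 16 of 20 cases and rose in 0, 3 and 3 (camera adjusted p = 1.97e-07, 8.78e-07 and 0.000325, and adjusted p = 0.0178, 0.0416 and 0.0935 with an estimated correlation). CXCL12, a chemokine gene, fell (-3.93, -4.63 and -1.26), as did LIF (-2.11 at 24 h and -3.58 at 72 h). Histone genes rose in 14, 14 and 12 of 14 cases with none down (adjusted p = 6.95e-09, 5.36e-07 and 7.86e-05, and adjusted p = 0.0173, 0.0416 and 0.0935 with an estimated correlation). HIST1H2BD rose by 3.35, 4.57 and 5.08 and HIST2H2BE by 3.17, 3.63 and 3.25. Histone genes are near copies of each other, so the split of fragments between single members is uncertain. ATF4 targets and amino acid synthesis genes fell in 11, 15 and 14 of 15 cases and rose in 1, 0 and 0 (adjusted p = 0.019, 1.96e-10 and 2.25e-07, and adjusted p = 0.383, 0.0092 and 0.0295 with an estimated correlation). The pseudokinase gene TRIB3 and CHAC1 fell (-1.48, -4.17 and -4.62 and -1.62, -4.82 and -3.48). P53 targets fell in 15, 9 and 15 of 17 cases and rose in 0, 5 and 1 (adjusted p = 0.00163, 0.097 and 9.01e-06, and adjusted p = 0.0173 and 0.00104 with an estimated correlation at 24 and 72 h). GDF15, which encodes a stress-induced cytokine, went from 287 ± 8.34 to 3.94 ± 0.138 FPKM at 72 h (-3.45 at 48 h and -6.02 at 72 h), and AEN fell (-1.72, -1.57 and -2.70). Interferon-stimulated genes fell in 10, 8 and 12 of 17 cases and rose in 2, 6 and 3 (adjusted p = 0.293, 0.169 and 0.00754, and adjusted p = 0.0935 with an estimated correlation at 72 h). The antiviral regulator IRF7 rose (1.97, 2.29 and 0.75) and IFI44 fell (-1.24, -1.68 and -1.94).

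Proliferation genes were down in 25 of 28 cases at 24 h and up in 27 and 28 at 48 and 72 h, with medians of -0.93, 1.29 and 1.52. The list passed at each time (adjusted p = 2.4e-05, 4.59e-08 and 7.33e-09, and adjusted p = 0.447, 0.25 and 0.188 with an estimated correlation). TOP2A fell by 0.73 at 24 h and rose by 1.97 and 2.90. Its level at 48 h was 23.4 ± 2.08 FPKM with JQ1, 5.63 ± 0.441 with TGF-β1 and 132 ± 7.16 in untreated cultures at 0 h. The cyclin gene CCNE2 rose at each time (0.35, 1.17 and 1.48). Cholesterol and fatty acid synthesis genes rose in 6, 13 and 20 of 21 cases and fell in 13, 3 and 0 (adjusted p = 0.521, 0.0446 and 1.98e-07, and adjusted p = 0.457 and 0.0935 with an estimated correlation at 48 and 72 h). The 48 h call of this list was lost without TGF-β1 plus JQ1 replicate 1 (median 0.23). FASN, which encodes fatty acid synthase, and INSIG1, a sterol feedback gene, rose at each time (0.62, 2.17 and 3.08 and 0.84, 1.33 and 2.94). Endoplasmic reticulum chaperone genes fell in 8, 4 and 12 of 15 cases and rose in 0, 7 and 2 (adjusted p = 0.0697, 0.676 and 0.00391, and adjusted p = 0.218 with an estimated correlation at 72 h). TPM scaling, to 1 total of length-scaled values per library, turned the 48 h counts to 5 up and 6 down. XBP1, a regulator of the unfolded protein response, and the chaperone gene DNAJB11 fell (-1.21, -2.21 and -2.79 and -1.05, -0.19 and -0.87), and HSPA5 fell at 72 h (-2.15). Autophagy and lysosome genes rose in 11, 13 and 10 of 18 cases and fell in 5, 4 and 7 (adjusted p = 0.0313, 0.0412 and 0.382, and adjusted p = 0.383 and 0.25 with an estimated correlation at 24 and 48 h). The lysosomal channel gene MCOLN1 rose (0.19, 1.54 and 1.87) and the lysosomal regulator TFEB fell (-1.44, -1.51 and -0.86).

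MYC itself rose by 0.17 at 24 h, did not pass at 48 h (0.01) and fell at 72 h (-0.16). At 48 h it passed as lower with TPM (-0.176) and quantile normalization (-0.137). MYC and ribosome biogenesis genes fell in 14, 13 and 14 of 20 cases and rose in 2, 5 and 5 (camera adjusted p = 0.081, 0.141 and 0.0206, and adjusted p = 0.318 with an estimated correlation at 72 h). The nucleolar genes NOP16 and PPAN fell (-0.82, -0.95 and -1.51 and -0.70, -0.72 and -1.26). AP-1 and immediate early genes rose in 11, 4 and 4 of 15 cases and fell in 3, 7 and 10 (adjusted p = 0.000894, 0.224 and 0.0186, and adjusted p = 0.383 and 0.349 with an estimated correlation at 24 and 72 h). EGR1 rose (3.53, 1.19 and 0.67) and JUNB fell (-0.88, -1.07 and -1.04). YAP and TAZ targets rose in 9, 5 and 4 of 18 cases and fell in 7, 8 and 12 (adjusted p = 0.236, 0.161 and 0.0311, and adjusted p = 0.318 with an estimated correlation at 72 h). ANKRD1 and AJUBA fell (-1.74, -2.69 and -2.93 and -0.75, -1.74 and -1.50). Growth factors and receptors did not pass (5, 6 and 12 of 21 up, 14, 11 and 7 down, adjusted p = 0.175, 0.097 and 0.398). VEGFA fell (-1.28, -1.84 and -2.78), as did FGF2, a fibroblast growth factor gene (-0.70, -1.50 and -3.31). BET proteins and P-TEFb regulators did not pass (2, 7 and 5 of 10 up, 5, 3 and 3 down, adjusted p = 0.349, 0.142 and 0.398), and median-of-ratios scaling turned the 24 h counts to 4 up and 1 down. BRD2 rose at each time (1.33, 1.49 and 0.76). BRD3 fell at 24 h (-0.12, but -0.014 with median-of-ratios scaling and 0.019 with quantile normalization) and rose at 48 and 72 h (0.32 and 0.37).

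Over all genes, the largest mean rises with JQ1 were those of HIST1H2BD, the imprinted gene PEG10 (3.64, 4.76 and 4.10), GPX3, which encodes a secreted glutathione peroxidase (1.01, 4.23 and 4.95), HIST2H2BE and ID1. The largest mean falls were those of AREG, which encodes the growth factor amphiregulin (-2.08, -5.23 and -6.03), the microfibril gene MFAP2 (-2.92, -5.10 and -4.68), WISP1 (-3.68, -4.83 and -3.98), PAPPA, a protease gene for IGF-binding proteins (-3.56, -3.86 and -4.94), and GDF15. At 24, 48 and 72 h, 10026, 10515 and 11224 of 13875 genes passed (3725, 5935 and 5809 up, 6301, 4580 and 5415 down), 1424, 2162 and 3186 with at least a 2-fold difference. The 24 h count of 1424 became 2231 with a pseudocount of 0.1, 954 with 1, 2216 with TPM and 2499 with voom. At all 3 times 2394 genes rose and 2954 fell. Camera passed 7, 11 and 17 of the 22 lists, and 3, 3 and 2 with an estimated correlation. Adjusted over the list alone, the protease list had 6 and the AP-1 list 4 members down at 24 h, the growth factor list 7 up at 48 h and the interferon list 4 up at 72 h, and the other counts equalled those over all genes. The balance depended on scaling. TPM gave 4846 genes up and 6454 down at 72 h. It gave 4363 genes up and 5917 down at 48 h and moved the median over all genes from 0.078 to -0.086, and at 24 h quantile normalization gave 5110 up and 4949 down. TGF-β1 plus JQ1 replicate 3 at 72 h stood apart from its 2 partners, with a chi-square per degree of freedom of 31 and 31.9 against a median of 6.97 over 30 replicate pairs. Without it 11236 genes passed at 72 h.

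**Figure D2:**
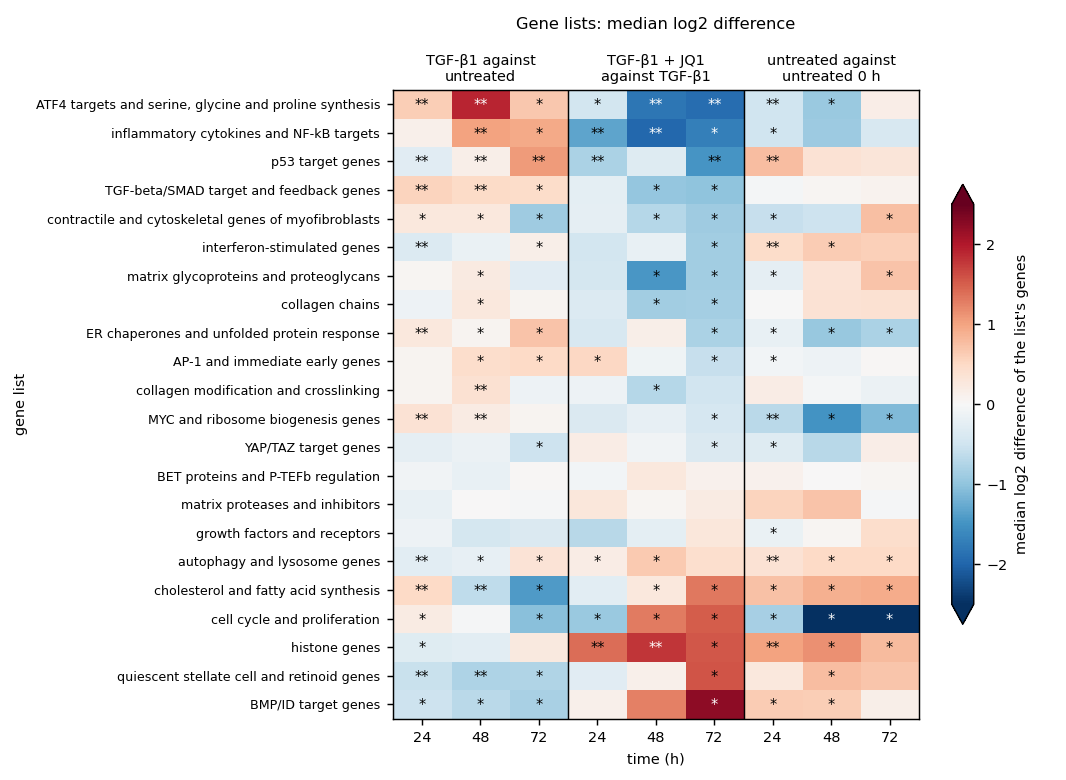
Colour gives the median log2 difference of the measured genes of 22 gene lists at 24, 48 and 72 h in 3 comparisons, with 1 star where camera passed and 2 where it also passed with an estimated correlation. ATF4 targets stood at 1.91 with TGF-β1 at 48 h and at -1.90 with JQ1 at 72 h, and histone genes stood at 1.39, 1.79 and 1.55 with JQ1.

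**Figure D3:**
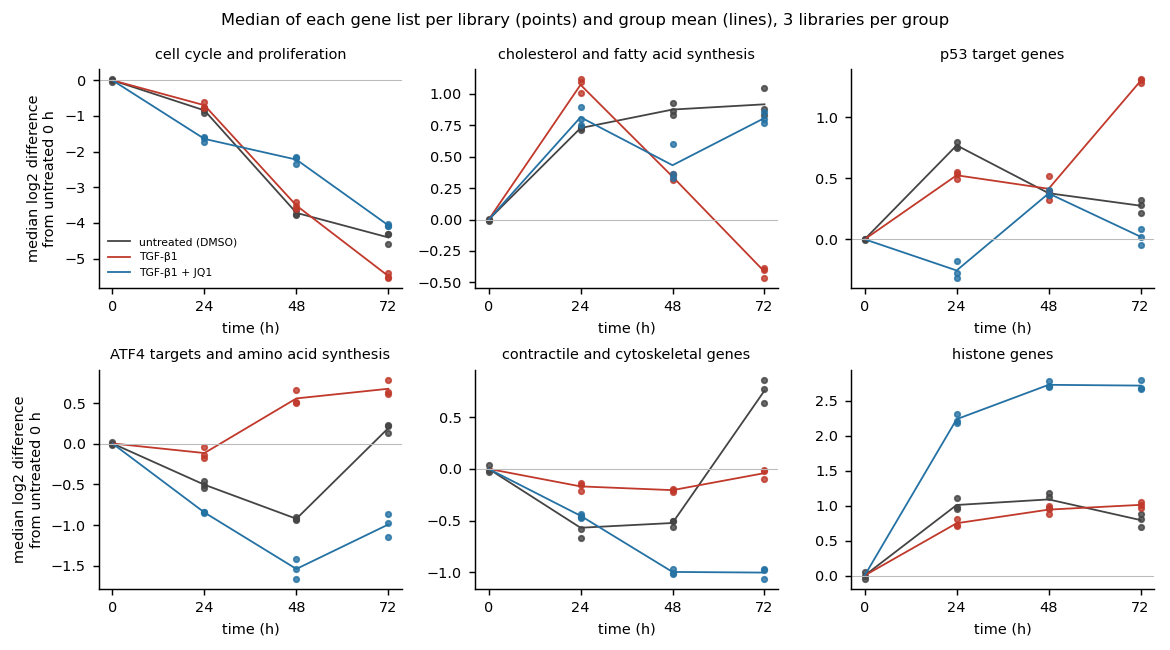
Median log2 difference of 6 gene lists from the untreated 0 h mean against time in h, with 1 point per library, 3 libraries per group and lines through the group means. Proliferation genes lay -4.41 from 0 h in untreated cultures at 72 h, and the contractile list lay 0.76 from 0 h there.

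Setting both effects side by side addresses how far JQ1 moved the genes that TGF-β1 moved. Of the genes raised by TGF-β1 and lowered by JQ1 at all 3 times, named here are the 6 with the largest mean TGF-β1 rise. The size of the JQ1 effect and the genes lowered by TGF-β1 did not enter this choice. Among these 6, CHAC1, a stress gene of the ATF4 list, and VDR went up with TGF-β1 and down with JQ1 (-2.67, -3.62 and -4.17 for VDR). MSC (-2.02, -3.05 and -4.32), FIBIN (-3.19, -3.04 and -5.45), the calcium pump gene ATP2A3 (0.97, 1.88 and 3.56 with TGF-β1 and -0.64, -2.05 and -4.16 with JQ1) and ADM2, which encodes a peptide hormone (1.20, 3.78 and 0.92 and -1.49, -4.70 and -5.24), showed the same pattern. MT2A, which encodes a metal-binding metallothionein, rose with TGF-β1 (0.41, 1.17 and 0.53) and rose further with JQ1 (1.53, 2.20 and 1.12), to 3063 ± 111 FPKM at 24 h. HES6, NRIP3, FOXP4, TMEM206 and ZSWIM7 also rose with TGF-β1 at each time and were lowered by JQ1 at none. With TPM 3 of them fell with JQ1 at 72 h, NRIP3 (-0.3), TMEM206 (-0.199) and ZSWIM7 (-0.19). NRIP3 also fell then with array weights (-0.122) and without TGF-β1 replicate 3 (-0.162) or TGF-β1 plus JQ1 replicate 2 (-0.15). NRIP3 rose by 0.44, 0.37 and 1.09 and TMEM206, a chloride channel gene, by 0.36, 0.42 and 0.69, and the 48 h call of HES6 was lost without untreated 48 h replicate 3 (0.24).

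Of the genes raised by TGF-β1, JQ1 lowered 1802 of 2496 at 24 h (72.2%), 1322 of 1950 at 48 h (67.8%) and 3096 of 4263 at 72 h (72.6%), and it raised 311, 363 and 547. Of the genes lowered by TGF-β1, JQ1 raised 1989 of 4887 (40.7%), 3273 of 5590 (58.6%) and 3615 of 5340 (67.7%), and it lowered 1787, 1367 and 1000. Among the raised genes called lower with JQ1, 1130, 888 and 1895 ended below untreated cultures, 536, 335 and 843 did not differ from them by the test, and 136, 99 and 358 stayed above. Of genes raised at least 2-fold, JQ1 lowered 59 of 71, 179 of 189 and 355 of 380. Of genes lowered at least 2-fold, it raised 65 of 193 (33.7%), 153 of 311 (49.2%) and 643 of 880 (73.1%). At all 3 times 591 genes rose with TGF-β1, of which 388 fell with JQ1 at all 3 times and 28 at none, and 2093 fell, of which 727 rose with JQ1 at all 3 times. Lists of these sizes drawn independently share 1133.5, 643.7 and 1663.7 genes in the first case and 1312, 2391.1 and 2235.7 in the second. The same 3 TGF-β1 libraries enter both effects with opposite sign, so their sampling error adds to the opposite calls. The covariance of the estimated effects was -0.0074, -0.0075 and -0.0074 in 50 simulations of unchanged groups with the measured spread, against -0.0543, -0.129 and -0.356 in the data. With median-of-ratios scaling the 48 h counts were 2135 raised and then lowered and 2007 lowered and then raised. These names stand for opposite signs of the TGF-β1 and JQ1 effects, not for an order in time.

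**Figure D4:**
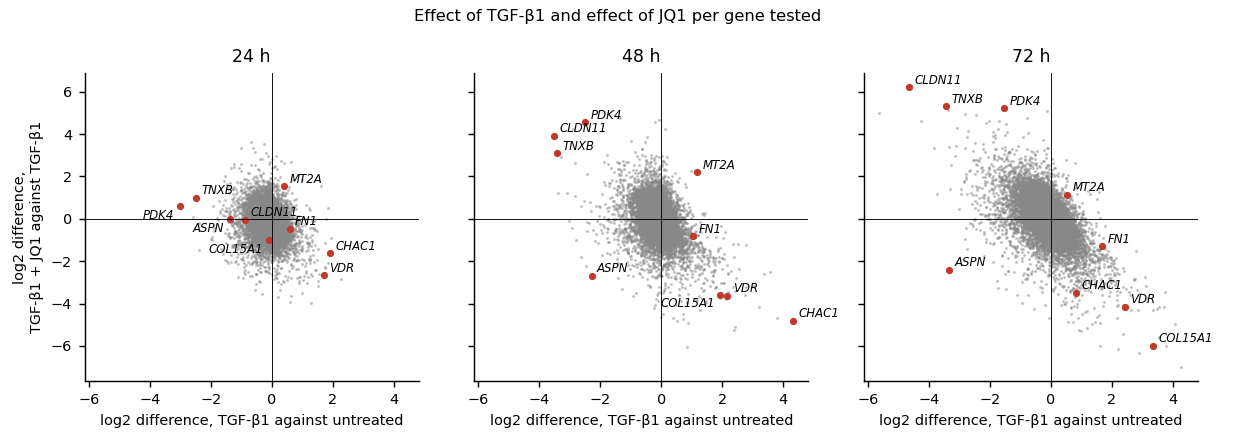
Log2 difference with JQ1 on top of TGF-β1 against log2 difference with TGF-β1 for 13875 genes at 24, 48 and 72 h, 1 point per gene, with 9 named genes in red. CHAC1 lay at 4.32 and -4.82 at 48 h, CLDN11 at -4.66 and 6.21 at 72 h, and MT2A on the positive side of both axes.

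TGF-β1 plus JQ1 against untreated cultures addresses how far the treated cells stood from cultures that received neither. ACTA2 was lower than in untreated cultures at each time (-0.88, -1.11 and -3.43), by the most at 72 h, at 16.9 ± 0.603 against 189 ± 30.9 FPKM (SE 0.07, adjusted p = 1.63e-22). FN1 differed from untreated cultures by 0.12 at 24 h without passing and was higher by 0.22 and 0.38 at 48 and 72 h. TIMP1 was higher at each time (1.83, 2.54 and 1.46). The largest mean rises were those of HIST1H2BD (2.74, 4.36 and 4.95), PEG10 (2.95, 3.404 and 2.67), DHRS3, which encodes a retinaldehyde reductase (1.06, 4.58 and 3.31), and HIST2H2BE (2.61, 3.10 and 3.02). The largest mean falls were those of WISP1 (-3.47, -4.32 and -4.92), CEMIP, a hyaluronan-degrading gene (-3.25, -4.25 and -5.01), FAM198B (-3.28, -4.43 and -4.34) and CYP1B1, a cytochrome gene (-3.26, -4.30 and -4.33).

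Histone genes were higher in 13, 13 and 14 of 14 cases with none lower (camera adjusted p = 2.99e-08, 5.38e-08 and 2.88e-07, and adjusted p = 0.0236, 0.0625 and 0.039 with an estimated correlation). Collagen chains were lower in 15, 14 and 17 of 20 cases and higher in 4, 3 and 2 (adjusted p = 0.126, 0.00292 and 1.84e-05, and adjusted p = 0.488 and 0.221 with an estimated correlation at 48 and 72 h). Contractile genes were lower in 8, 13 and 15 of 17 cases and higher in 5, 4 and 1 (adjusted p = 0.668, 0.06 and 7.67e-06, and adjusted p = 0.154 with an estimated correlation at 72 h). Inflammatory genes were lower in 20, 16 and 16 of 20 cases and higher in 0, 2 and 3 (adjusted p = 5.06e-06, 0.000742 and 0.00172, and adjusted p = 0.0456, 0.292 and 0.154 with an estimated correlation). ATF4 targets were higher in 7, 5 and 0 of 15 cases and lower in 7, 7 and 15 (adjusted p = 0.364, 0.819 and 6.1e-07, and adjusted p = 0.039 with an estimated correlation at 72 h). P53 targets were lower in 16, 7 and 11 of 17 cases and higher in 0, 8 and 5 (adjusted p = 7e-06, 0.819 and 0.141, and adjusted p = 0.000916 with an estimated correlation at 24 h). Proliferation genes were lower in 22 of 28 cases at 24 h and higher in 27 and 19 at 48 and 72 h (adjusted p = 0.00403, 2.46e-10 and 0.00177, and adjusted p = 0.758, 0.414 and 0.46 with an estimated correlation). At 24, 48 and 72 h, 9956, 10046 and 10561 genes passed (2995, 4639 and 5094 up, 6961, 5407 and 5467 down), 1620, 1948 and 2133 with at least a 2-fold difference. The 24 h count of 1620 became 2411 with a pseudocount of 0.1, 1098 with 1, 2438 with TPM and 2638 with voom. Camera passed 9, 5 and 10 lists, and 3, 0 and 2 with an estimated correlation. Adjusted over the list alone, 6 contractile and 8 ATF4 genes were up at 24 h, with equal counts for the other lists named here. With median-of-ratios scaling the 24 h counts were 4859 up and 5091 down, and the median over all genes moved from -0.173 to -0.003, while TPM at 48 h gave 3441 up and 6730 down. Median-of-ratios scaling turned the balance at 48 and 72 h (5139 up and 5007 down, 5451 up and 5179 down), and quantile normalization turned it at each time (5309 and 4624, 5660 and 4626, and 5820 and 4884).

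**Figure D5:**
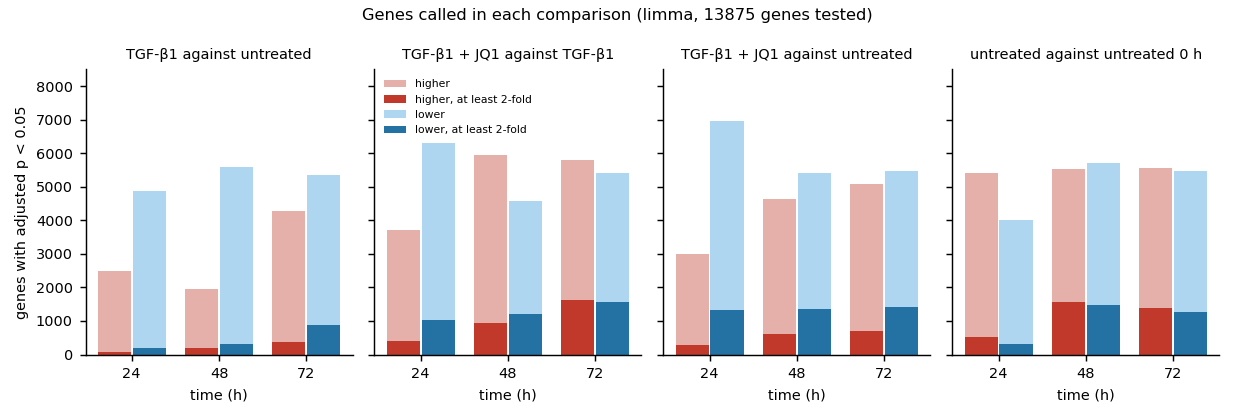
Number of genes with an adjusted p under the threshold in each comparison at 24, 48 and 72 h out of 13875 genes tested, with bars for higher and lower genes and a darker part for those with at least a 2-fold difference. The 2-fold part grew from 264 genes at 24 h to 1260 at 72 h for TGF-β1 against untreated cultures and from 1424 to 3186 for JQ1 against TGF-β1 alone. With a pseudocount of 0.1 it grew from 530 to 1842 and from 2231 to 4076, and with voom from 688 to 2047 and from 2499 to 4327. With median-of-ratios scaling the 24 and 48 h bars of TGF-β1 were near equal.

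Whether each effect differed between 72 and 24 h was tested as a difference of differences. The TGF-β1 effect on CTGF fell from 1.61 at 24 h to -2.06 at 72 h (difference -3.66, SE 0.12, adjusted p = 1.09e-17), and that on ACTA2 from 0.39 to -0.89 (difference -1.28). IL1RL1, the receptor gene for interleukin-33, rose by 4.25 at 72 h and differed by -0.34 at 24 h (difference 4.59). The tight junction gene CLDN1 showed a difference of 4.13, GDF15 of 3.92 and the lysosomal membrane gene LAMP3 of 3.85. The TGF-β1 effect grew more negative for INMT, a methyltransferase gene (-4.54), IGSF10 (-3.82), CLDN11 (-3.79) and FABP3, which encodes a fatty acid binding protein (-3.70). The JQ1 effect on PDGFRB differed by 3.06. Its largest positive differences were those of CLDN11 (6.25), INMT (6.05), LRRC17 (6.03) and the ankyrin gene ANK3 (5.96). The largest negative ones were those of the pentraxin gene PTX3 (-7.20), IL1RL1 (-6.72), PCDH1 (-5.35) and GPR1 (-5.34). The TGF-β1 effect differed for 8444 genes (4443 more positive and 4001 more negative at 72 h) and the JQ1 effect for 9818 (5962 and 3856), and 1201 and 2628 of them by at least 2-fold (1756 and 3298 with a pseudocount of 0.1, 848 and 2087 with a pseudocount of 1, 1752 and 3197 with TPM and 1930 and 3475 with voom). The balance turned to 4084 and 4408 with median-of-ratios scaling for TGF-β1 and to 4814 and 4887 with quantile normalization for JQ1. Camera passed 14 and 12 lists, or 4 and 2 with an estimated correlation.

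Markers of other liver cell types were measured as levels. Of 13 hepatocyte markers APOA1 alone was tested, with group means from 0.05 to 14.6 FPKM and differences of 1.23, 3.67 and 4.75 with JQ1 against TGF-β1, and the other 12 stayed at or under 0.14 FPKM in every group. None of 8 lymphocyte markers was tested, the highest group mean being 0.828 FPKM, and of 11 macrophage markers CD14 was, at 0.285 to 1.95 FPKM. Of 8 mesothelial markers WT1, PODXL and CALB2 were tested, and 2 of these 3 rose with JQ1 against TGF-β1 at 48 and at 72 h. Of 9 cholangiocyte and epithelial markers 5 were tested, KRT18 at 30.4 to 238 FPKM, and all 5 fell with TGF-β1 at 72 h (adjusted p = 0.00218, and adjusted p = 0.0488 with an estimated correlation). These marker genes lie outside the rule for named genes, and those named here were chosen after their values were seen.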

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

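The tests of depth, of library scaling, of portal fibroblast and smooth muscle markers and of a rise in untreated cultures were chosen only after the result was seen. The test of abundant genes, the 2 exchanges of libraries, the slower course and the splits were written before their results. Listed here are results whose effect differed between 72 and 24 h by the test of that difference: the 2 counts, named genes that differed by at least 4-fold with an adjusted p past the threshold, and lists that passed with an estimated correlation. With 3 libraries per group, no library is listed here for lying far from its group.

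The TGF-β1 effect differed between 72 and 24 h for 8444 genes (60.9%). Of 74 named genes 57 did, 14 by at least 4-fold, and 8 went in opposite directions. In log2, lower at 72 h were CTGF (-3.66), LMOD1 (-2.04), COLEC11 (-2.06), IGFBP5 (-2.11), CLDN11 (-3.79), INMT (-4.54), IGSF10 (-3.82) and FABP3 (-3.7). Higher were FAM46A (3.24), IL1RL1 (4.59), CLDN1 (4.13), GDF15 (3.92), LAMP3 (3.85) and ATP2A3 (2.59). By list median, interferon-stimulated genes (0.58), p53 targets (1.35) and autophagy and lysosome genes (0.66) were higher and cholesterol and fatty acid synthesis genes (-1.8) lower.

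The JQ1 effect differed for 9818 genes (70.8%). Of 79 named genes 75 did, 28 by at least 4-fold, and 9 went in opposite directions. Lower at 72 h were COL16A1 (-2.63), COL15A1 (-4.97), MYL9 (-3.01), EGR1 (-2.86), EGR2 (-2.65), FGF2 (-2.61), TRIB3 (-3.15), GDF15 (-3.52), AREG (-3.95), PTX3 (-7.2), IL1RL1 (-6.72), PCDH1 (-5.35), GPR1 (-5.34), ATP2A3 (-3.52), MSC (-2.3), FIBIN (-2.27) and ADM2 (-3.75). Higher were PDGFRB (3.06), TNXB (4.3), RARB (2.32), CXCL12 (2.67), FASN (2.45), INSIG1 (2.1), GPX3 (3.94), CLDN11 (6.25), INMT (6.05), LRRC17 (6.03) and ANK3 (5.96). By list median, ATF4 targets (-1.32) and p53 targets (-0.67) were lower.

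With TGF-β1 at 48 h more genes were lower (5590) than higher (1950). This excess depends on library scaling: with median-of-ratios scaling and with quantile normalization the counts were near equal, as given above. Both recentre each library, so they cannot tell a shift of most genes from an effect of scaling. A difference in depth is argued against, since the mean depth of the 2 groups differed by 0.28%. A few abundant genes taking fragments stay open: the 10 most abundant genes held 25.1% of the assigned fragments with TGF-β1 and 20% in untreated cultures at 48 h, and with these genes left out of each total 43.1% of the calls were higher, between the bounds of 45% and 40% written beforehand. No biological explanation was tested, since without counts of RNA per cell the values cannot show a change of all genes.

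Proliferation genes were lower with JQ1 at 24 h and higher at 48 and 72 h. Library scaling is argued against by a list median of 1.23 at 48 h with median-of-ratios scaling. An exchange of the 24 and 48 h libraries with JQ1 is argued against by 775 other genes that moved alike in untreated and TGF-β1 cultures from 24 to 48 h, of which 91.5% moved that way with JQ1. Proliferation genes fell with time in untreated cultures, and a slower course with JQ1 may account for the 48 and 72 h part. It is argued against at 24 h, where list medians from 0 h were -1.722 to -1.601 with JQ1 and -0.768 to -0.599 with TGF-β1. Of 517 genes outside the list that rose at least 2-fold from 24 to 48 h in untreated cultures, 70.8% were lower with JQ1 than with TGF-β1 at 48 h, against 44.5% of the 13847 genes outside the list. An effect of JQ1 on division itself remains open and untested, and so does an effect of JQ1 alone, for which no arm was analysed.

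Contractile genes were lower with TGF-β1 than in untreated cultures at 72 h. An exchange of the untreated and TGF-β1 libraries at 72 h is argued against by the 43 genes raised at least 2-fold at both earlier times, of which 79.1% were called higher at 72 h. Library scaling is argued against by a list median of -0.85 with median-of-ratios scaling. Portal fibroblasts or smooth muscle cells in the untreated 72 h cultures stay open. Their 4 tested markers outside the list did not rise together in untreated cultures from 48 to 72 h, with a median change of -0.06 (THY1 0.01, NOTCH3 0.23, MCAM -0.13, CSPG4 -0.37). At 72 h all 4 were lower with TGF-β1 than in untreated cultures, as these cells would need (THY1 -1.44, NOTCH3 -2.27, MCAM -1.07, CSPG4 -1.25). A rise in the untreated cultures after 48 h may account for the pattern. The list rose by a median of 1 from 48 to 72 h in untreated cultures, against 0.1 with TGF-β1 and -0.02 with JQ1, but the bound of 1 was set after these values were seen and the value lies at the bound. Why untreated cultures rose was not tested.

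With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of these 12 comparisons 1 split, the real one, gave as many genes. For TGF-β1 against untreated the real counts were 7383, 7540 and 9603 and the highest others 0, 0 and 1. For JQ1 against TGF-β1 they were 10026, 10515 and 11224 against 0, 1 and 0, for JQ1 against untreated 9956, 10046 and 10561 against 0, 0 and 27, and for untreated cultures against 0 h 9421, 11211 and 11049 against 0, 0 and 0.

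For the other counts 100 splits were drawn. For the difference of the TGF-β1 effect 1 split gave as many genes (8444, highest other 7484). For that of the JQ1 effect 2 did (9818, highest other 11312, with the labels exchanged at 1 time). These shares lie under 0.05. Splits that mix the groups widen the spread within them and so give few calls. A low share therefore shows that the groups differ, and not that an effect changed with time. For genes raised by TGF-β1 and lowered by JQ1 at 24 h 5 splits, counted with the real one, gave as many (1802, highest other 2816), a share that is not under 0.05, so chance is not excluded at that share. The bound written beforehand counted the other splits alone, of which 4 of 99 (4.04%) gave as many, and by that count the share lies under the bound. The verdict on this count turns on whether the real split is counted. For genes lowered and then raised at 24 h 4 splits did (1989, highest other 5706). At 48 h 4 did for raised and then lowered (1322, highest other 4384) and 3 for lowered and then raised (3273, highest other 4119), and at 72 h 2 and 2 did (3096, highest other 4206, and 3615, highest other 4178). For these 5 counts the share lies under 0.05, which shows that the groups differ and not that JQ1 opposes TGF-β1. Each highest other exceeds the real count and has the TGF-β1 plus JQ1 libraries in the middle place. In the case of 1802 the untreated libraries stand there. The middle place was recorded for the highest split of each count alone, so it is not known for the other splits that gave as many.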

How the results depend on the processing

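Precision weights on recovered fragments (voom) and the fit of protein-coding genes alone were chosen only after the result was seen. All other alternatives here, like the contrasts, lists and named-gene rule, were chosen before the data were examined. Tools for counts were not run as main tests, since no counts were available, and voom used fragments recovered from FPKM.

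Of the recomputed counts of genes past the threshold 397 stayed within 1.5 times the reported one and 13 did not. With the filter at 5 FPKM the counts for JQ1 against TGF-β1 were 6634, 6863 and 7236 at 24, 48 and 72 h, for JQ1 against untreated 6432, 6536 and 6790, and for untreated cultures against 0 h 6185, 7256 and 7149, because fewer genes were tested. Genes raised and then lowered at 48 h numbered 2135 with median-of-ratios scaling and 2178 with quantile normalization (1322 reported), and genes lowered and then raised 2007 and 2067 (3273 reported). These scalings recentre each library, which moves the median over all genes at 48 h from -0.111 to -0.005 and 0.005.

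Of 182 recomputed 2-fold counts, 156 stayed within 1.5 times and 26 did not. For TGF-β1 against untreated, 264 became 530 with a pseudocount of 0.1, 165 with 1, 511 with TPM and 688 with voom, 500 became 751 with 0.1 and 828 with voom, and 1260 became 2047 with voom. For JQ1 against TGF-β1, 1424 became 2231 with 0.1, 2216 with TPM and 2499 with voom. For JQ1 against untreated, 1620 became 2438 with TPM and 2638 with voom. For untreated cultures, 828 became 1466 with 0.1, 510 with 1, 1421 with TPM and 1742 with voom. For the difference of the TGF-β1 effect, 1201 became 1930 with voom. With the filter at 5 FPKM the 2-fold counts were 930, 1392 and 2075 for JQ1 against TGF-β1, 994, 1178 and 1323 for JQ1 against untreated and 544, 2020 and 1737 for untreated cultures, because fewer genes were tested. A larger pseudocount shrinks the differences of genes with low values, and the cause of the other moves was not tested.

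The balance of higher and lower genes also turned under alternatives other than scaling. Without the filter JQ1 against TGF-β1 at 48 h had 6844 up and 6863 down, and untreated cultures at 48 h had 8894 up and 6523 down. With the filter at 5 FPKM JQ1 against untreated at 48 h had 3400 and 3136, and untreated cultures at 72 h 3078 and 4071. Array weights gave 5534 and 5513 for JQ1 against untreated and 5926 and 5941 for untreated cultures at 72 h. Protein-coding genes alone gave 4830 and 4831 for JQ1 against TGF-β1 and 4409 and 5098 for untreated cultures at 72 h.

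Of named-gene results, 9047 stayed on their side of the threshold, 70 lost it and 22 gained it. The other 3 were called and changed sign with quantile normalization, whether or not the new value passed. They were COL1A2 with TGF-β1 at 48 h (0 against 0.257), COL3A1 with JQ1 at 72 h (0.05 against -0.215) and BRD3 with JQ1 at 24 h (0.019 against -0.124). Among those gained, some passed with the other sign. These were COL1A1 with JQ1 at 24 h (-0.62 with quantile normalization against 0.172) and MYC with JQ1 at 48 h (-0.176 with TPM and -0.137 with quantile normalization against 0.006). The cause was not tested. Of list results 6263 stayed, 216 lost and 253 gained the threshold. An estimated correlation ended 118 list calls and left 190 of 308 list results on their side, and fry, which does not compare a list with other genes, added 127. The median over all genes moved by over 0.1 as well for JQ1 against TGF-β1 (from -0.113 to 0.018 with quantile normalization at 24 h, from 0.078 to -0.086 and from 0.034 to -0.125 with TPM at 48 and 72 h), for JQ1 against untreated (from -0.173 to -0.003 with median-of-ratios scaling at 24 h, from -0.037 to -0.18 and from -0.012 to -0.112 with TPM) and for the difference of the JQ1 effect (from 0.142 to 0 with quantile normalization).

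With 1 library left out, lowest to highest, TGF-β1 against untreated gave 6355 to 7052, 6808 to 7021 and 9080 to 9212 genes. JQ1 against TGF-β1 gave 9622 to 9714, 10178 to 10257 and 10920 to 11236, JQ1 against untreated 9483 to 9617, 9580 to 9739 and 10164 to 10606, and untreated cultures against 0 h 8826 to 9155, 10857 to 10984 and 10712 to 10807. The differences of effects gave 8016 to 8314 for TGF-β1 and 9539 to 9927 for JQ1. Raised and then lowered genes gave 1486 to 1797, 1207 to 1331 and 2873 to 3105, and lowered and then raised genes 1709 to 1994, 2895 to 3243 and 3386 to 3687.

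Of 2964 named-gene results with 1 library left out, 30 lost the threshold and 3 gained it. With TGF-β1 at 24 h, TIMP1 was lost without untreated replicate 1 (0.18) or 3 (0.17) or TGF-β1 replicate 2 (0.16) or 3 (0.15), and COL1A2 without untreated replicate 2 (-0.16) or 3 (-0.15) or TGF-β1 replicate 1 (-0.13) or 2 (-0.17). At 48 h LOXL1 was lost without untreated replicate 1, 2 or 3 (-0.21 each) or TGF-β1 replicate 1 (-0.18) or 2 (-0.21), and HES6 without untreated replicate 3 (0.24). At 72 h TIMP1 was lost without untreated replicate 1 (0.14) or TGF-β1 replicate 3 (0.15), BRD3 without untreated replicate 1 (-0.05) or TGF-β1 replicate 1 (-0.08) or 3 (-0.09), HIST2H2BE without untreated replicate 1 (-0.16) and COL1A2 without TGF-β1 replicate 1 (-0.16). With JQ1 at 24 h SMAD7 was lost without TGF-β1 replicate 2 (-0.20) or 3 (-0.11) or JQ1 replicate 1 (-0.12) or 3 (-0.22), and EGR2 without TGF-β1 replicate 2 (-0.22) or 3 (-0.15) or JQ1 replicate 2 (-0.23) or 3 (-0.23), and at 72 h HES6 without JQ1 replicate 3 (0.14). List calls lost, with their medians, were histone genes (-0.31, without untreated 24 h replicate 3), interferon-stimulated genes (0.18, untreated 72 h replicate 1) and YAP targets (-0.52, untreated 72 h replicate 2) with TGF-β1, and cholesterol genes with JQ1 at 48 h (0.23, JQ1 replicate 1). Without untreated 24 h replicate 1, matrix glycoproteins (-0.20) and growth factors (-0.15) were lost in untreated cultures at 24 h and growth factors (-0.30) for the difference of the TGF-β1 effect, and without untreated 24 h replicate 3, MYC genes (0.02) for JQ1 against untreated at 24 h. Inflammatory genes were lost for the difference of the TGF-β1 effect without untreated 24 h replicate 1 (0.46) or 3 (0.47), untreated 72 h replicate 1 (0.44), TGF-β1 24 h replicate 1 (0.50) or TGF-β1 72 h replicate 1 (0.47).

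The replicate number as a block changed 0 named-gene calls and 1 list call, and moved the counts over all genes, for example from 7383 to 7322 for TGF-β1 at 24 h and from 11049 to 11017 for untreated cultures at 72 h. Of 36 pairs of replicate numbers 2 had a correlation of residuals across genes over 0.1 (range -0.118 to 0.25), and in 0 of 12 comparisons did every pair, so the numbers were not used as pairs. With voom 7279 of the 7383 genes called for TGF-β1 at 24 h were shared, 7371 at 48 h and 9444 at 72 h. At these depths 3 fragments equal 0.0548 to 0.0805 FPKM on 1 kb, under the filter, and chi-square per degree of freedom between replicates had a median of 6.97, where counting error alone gives about 1.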

Other observations

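The gene families here were chosen only after their values were seen, and no explanation of them was tested. Counts are of genes past the threshold, in the order 24, 48 and 72 h.

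With JQ1 against TGF-β1, 5, 6 and 6 of 6 metallothionein genes rose (median 1.31, 1.89 and 1.39, and 1.41, 1.82 and 1.39 with median-of-ratios scaling). Both ferritin chain genes rose at each time (1.52, 1.49 and 1.18). FTL, which encodes the ferritin light chain, held 1.99% of the assigned fragments with JQ1 at 72 h and 0.444% with TGF-β1 alone. Of 13 mitochondrially encoded protein genes 6, 9 and 13 rose with JQ1 (0.07, 0.37 and 0.83, with 10 up at 24 h with median-of-ratios scaling). All genes of the mitochondrial chromosome together, protein-coding or not, held from 0.757% of the assigned fragments with TGF-β1 at 72 h to 1.72% with JQ1 at 48 h. Metallothionein and ferritin genes have near copies, so single members are uncertain.

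With TGF-β1 0, 0 and 4 of 5 HLA class I genes rose and 5, 4 and 0 fell (4, 3 and 0 fell with median-of-ratios scaling), with a median of 0.7 at 72 h. With JQ1 against TGF-β1 1, 1 and 1 rose and 2, 3 and 4 fell (median -1.38 at 72 h), or 2 up and 1 down at 24 h with that scaling. Of 83 cytosolic ribosomal protein genes, 28, 7 and 9 rose and 1, 4 and 54 fell with TGF-β1 (65, 49 and 10 up and 1, 1 and 51 down with median-of-ratios scaling). With JQ1 against TGF-β1 3, 35 and 41 rose and 68, 9 and 18 fell (8, 25 and 43 up and 54, 22 and 18 down with that scaling).

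Of 1308 long noncoding genes tested, 55.1, 58.6 and 59.6% were higher in untreated cultures than at 0 h, against 39.2, 38.8 and 38.7% of 11338 protein-coding genes, and 135, 224 and 192 were lower. With TGF-β1 6, 11 and 20.1% of the long noncoding genes rose and 38, 28.1 and 36.8% fell, against 21.1, 15.3 and 34.2% up and 36.6, 44.2 and 40.5% down among protein-coding genes. These genes have low values, and the strand setting of the counting is not given in the sources used here.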
